A study of Mus musculus with 36 samples.

How the data were processed

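The study compared total RNA of cochleae from sham-operated and adrenalectomized mice at 6 circadian times. Per the labels, RNA was made into strand-specific libraries of messenger RNA and sequenced as single reads on an Illumina HiSeq in pools of 6 libraries, and which libraries shared a pool is not given in the sources used here. The submitters' processing notes name the aligner STAR 2.4.0i and the mouse genome build mm10. The counting program, the annotation and the strand setting are not given in the sources used here. Without the strand setting, reads of overlapping and antisense genes cannot be told apart with certainty, and members of gene families such as immunoglobulin segments may have shared reads.

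The deposited table holds whole-number counts per Ensembl gene, not normalized by the authors, for 39017 genes and 36 libraries. Its other column is gene length per the file headers, and 0 further columns of samples were present. The times in the column names were 1 h earlier than those in the sample labels for 30 of the 36 columns. Each column was mapped by status, replicate number and the only labelled time within 1 h, and the labelled times were used. Gene symbols and coordinates came from GENCODE M21, built on GRCm38, to which 37693 IDs (96.6%) matched.

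Nothing in the labels says that libraries came from separate animals beyond the description of separate samples, so p-values measure the spread between these samples. Replicates within a group differed from each other by more than sampling noise (chi-square per degree of freedom from 5.49 to 22.7), so no library was counted as a duplicate. Mitochondrial genes held 2.25 to 2.71% of counts and the 10 most abundant genes 4.73 to 6.48%. No batch is given in the labels.

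Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr, glmQLFit and glmQLFTest). The filter kept 22556 genes, and the 16461 left out held 0.0779% of counts. Scaling factors lay between 0.981 and 1.03. A model with 12 group means, with 24 residual degrees of freedom, gave the comparison of ADX with sham over the mean of the 6 times and at each time. A model with a cosine and a sine of period 24 h per status gave the tests of rhythm in sham, in ADX, shared by both, and of the difference. Each test was adjusted over all tested genes by the Benjamini-Hochberg method, with a threshold of 0.05. Peak-to-trough values are fitted, on the log2 scale, and CPM are counts of the genes kept by the filter scaled by their TMM library sizes, computed here. The CPM of Gh in single libraries were scaled over all genes of the table.

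For 31 gene lists, limma 3.58.1 gave camera with a preset inter-gene correlation of 0.01 and with an estimated one, and fry. Fisher's exact test compared the share of rhythmic members with that of all other tested genes. The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 10 highest and 10 lowest log2 fold changes among genes past the threshold with a mean CPM of at least 1 and the same sign at all 6 times. It also took the glucocorticoid-induced, receptor and core clock genes, the 10 other genes with the smallest p of a shared rhythm, the 15 with the smallest p of a difference in rhythm, the most extreme called genes at each time, up to 4 members per list, and the markers of tissue makeup. Pituitary markers were added after the libraries had been looked at. The result of 1 gene that the rule takes is not reported here.

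The alternatives were DESeq2 1.42.0 and its size factors, no filter on low counts, the replicate number as a block, covariates for tissue makeup, an additive model, limma-voom, a test of any difference between the 6 times, a second cosine of 12 h, fits on the samples of a single status or time, an estimated correlation for the lists, and each library left out in turn. The times of the column names and the removal of 3 muscle-high libraries, of the 4 libraries of highest Gh, of the 5 libraries with Gh over 50 CPM and of 4 libraries picked by hand for pituitary transcripts were added after seeing the data.

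The tests of the mean comparison, of CT20, of rhythm in sham, in ADX and shared by both, of the difference in rhythm, of the amplitude ratio and of 1 raised list were tried on simulated counts with the means and library sizes of the real samples. Each gene was drawn independently with its own spread. Deviations shared by many genes of a library, such as those of carried-over tissue, were thus not simulated, and recovery in the real data may be lower. The other single times, the 5-df test and Fisher's exact test were not simulated. The comparison of ADX with sham recovered 58.2, 82.1 and 97.0% of genes changed by 0.3, 0.6 and 1 on the log2 scale, and the test of rhythm in sham 24.0, 62.0, 78.0 and 90.0% of genes with peak-to-trough values of 0.3, 0.6, 1 and 2. Figures were drawn with matplotlib 3.10.9.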

Results

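Gene expression was measured by RNA sequencing in the cochlea, the hearing organ of the inner ear, of CBA/Sca mice aged 12 weeks. The animals had either been adrenalectomized (ADX), which removes the adrenal source of glucocorticoids, or sham-operated. Tissue was taken at 6 circadian times (CT04, CT08, CT12, CT16, CT20 and CT24), with 3 libraries per status and time and 36 libraries in all. The deposited counts summed to between 18999408 and 28995197 per sham library and between 20351081 and 28947793 per ADX library. Some libraries held transcripts of neighbouring tissue. The skeletal muscle marker score, a mean centred log2 CPM, reached 4.13 in ADX CT20 replicate 3, 2.79 in ADX CT12 replicate 1 and 2.28 in ADX CT16 replicate 2. The pituitary hormone transcript Gh reached 1182 CPM in sham CT16 replicate 3, 492 CPM in sham CT08 replicate 3, 129 CPM in ADX CT24 replicate 2, 85.9 CPM in sham CT08 replicate 2 and 60.05 CPM in ADX CT24 replicate 1.

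The comparison of ADX with sham over the mean of the 6 times asked which cochlear transcripts depended on the adrenal glands regardless of the hour. Pla2g2d, a secreted phospholipase A2 expressed in lymphoid tissue (ENSMUSG00000041202, chromosome 4, 138775735 to 138782046), rose from 7.21 ± 2.46 CPM in sham to 16.6 ± 5.21 CPM in ADX (SD, n = 18 each), a log2 fold change of 1.21 ± 0.14 (SE). It ranked highest among called genes with a mean CPM of at least 1 and the same sign at all 6 times. Under that rule it was followed by variable segments of immunoglobulin chains, with log2 fold changes of 1.19 ± 0.26 for Igkv4-91, 0.85 ± 0.20 for Ighv1-63, 0.71 ± 0.17 for Igkv4-53 and 0.60 ± 0.10 for Ighv7-3. Ighv1-16, Tbata, Ighv2-6, Stmnd1 and Mybpc2, a myosin-binding protein of fast skeletal muscle, rose by between 0.49 and 0.59, and without the 3 libraries of highest muscle level Mybpc2 had a log2 fold change of 0.34 (edgeR adjusted p = 0.0310). Under the same rule, the transcripts that fell furthest included Thbs4, an extracellular matrix thrombospondin (ENSMUSG00000021702, chromosome 13, 92751590 to 92794818), which went from 21.8 ± 7.94 to 14.5 ± 3.199 CPM (log2 fold change -0.55 ± 0.08). Klk1, a tissue kallikrein, Nags, the N-acetylglutamate synthase of the urea cycle, the lectin Clec4b2 and the osteoblast gene Ifitm5 had log2 fold changes between -0.55 and -0.52. Col22a1, the myeloid chitinase-like gene Chil3, the bone sialoprotein gene Ibsp, Adamtsl2 and Ccno had values between -0.43 and -0.36.

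In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 162 of 22556 genes passed an adjusted p of 0.05, 78 higher and 84 lower in ADX. Their median absolute log2 fold change was 0.25, 9 exceeded 1.5-fold, and 112 had the same sign at all 6 times. The adjusted p was 3.1e-05 for Pla2g2d, 0.0015 for Thbs4 and 0.0074 for Ighv7-3, and these 3 genes passed in each of the 36 fits that left out a library. The other genes named above passed in between 10 (Ifitm5 and Nags) and 33 (Mybpc2) of these fits, with Klk1 and Stmnd1 in 11, Igkv4-53 in 12 and Ighv1-63 in 13. Immunoglobulin segments are near-identical copies whose reads the counting could have split, so their single values are uncertain. Removing the 4 libraries of highest Gh, or the 5 with Gh over 50 CPM, leaves only replicate 1 at sham CT08. Its B lymphocyte score of -0.82 was the lowest of the 36 libraries, so the results of these sets also rest on it. The count of called genes depended on the libraries used: leaving out 1 library gave between 15 and 299. Without the 4 libraries of highest Gh it was 165 (131 higher, 34 lower), of which 67 were among the 162, and without the 5 with Gh over 50 CPM it was 9, of which 7 were. Without 4 libraries picked by hand for pituitary transcripts (ADX CT24 replicates 1 and 2, sham CT08 replicate 3 and sham CT16 replicate 3) it was 5, namely Pla2g2d, Thbs4, Clec4e, Gucy1a1 and Cfb (the last 3 named after their values were seen). With 1 library left out, it moved by over 1.5 times without ADX CT04 replicates 1 (76) and 3 (31), ADX CT08 replicate 3 (60), ADX CT12 replicate 3 (27), ADX CT16 replicates 1 (106) and 2 (20), ADX CT20 replicate 3 (271), ADX CT24 replicate 1 (15), sham CT04 replicates 1 (83) and 2 (21), sham CT08 replicate 3 (53), sham CT12 replicates 2 (92) and 3 (29), sham CT16 replicates 2 (82) and 3 (56), sham CT20 replicates 1 (299), 2 (81) and 3 (23), and sham CT24 replicates 1 (93) and 2 (37). DESeq2 called 645 genes and a fit with tissue makeup covariates 682. The covariates were a skeletal muscle score and a marrow score, the mean of erythroid, granulocyte precursor and B lymphocyte genes. The scores of these kinds differed in ADX by -0.17, -0.21 and 0.28, so their mean does not adjust for a shift between them.

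Among gene groups fixed beforehand, all 15 measured B lymphocyte markers had a positive log2 fold change, with a median of 0.30. The set test camera gave this list adjusted p = 5.5e-11 with a preset correlation and adjusted p = 0.384 with an estimated correlation. Ighm, the heavy chain of IgM, rose from 874 ± 129 to 1097 ± 203 CPM (SD, n = 18 each), and Ms4a1, Cd79a and Cd22 had log2 fold changes of 0.29, 0.31 and 0.24. Of the B lymphocyte list, 1 member passed over all genes (Ighm, adjusted p = 0.0489 in edgeR) and 13 adjusted over the list alone. Neutrophil and granulocyte precursor genes had a median of -0.19 and a negative value for each of 15 members (camera adjusted p = 1.6e-11 with the preset and adjusted p = 0.384 with an estimated correlation). Of these, 3 passed over all genes, Chil3, Retnlg and Mmp8, which fell by 0.39, 0.25 and 0.25 on the log2 scale, and 15 members passed adjusted over the list alone. Osteoblast and bone matrix genes had a median of -0.22 over 12 members (camera adjusted p = 5.5e-11 with the preset and adjusted p = 0.176 with an estimated correlation). Ibsp fell by 0.39 and Dmp1 by 0.24, the only 2 to pass over all genes, and 11 passed adjusted over the list alone. Bglap and Bglap2, which encode osteocalcin, had log2 fold changes of -0.41 and -0.41. The osteoblast score stood at 0.11, 0.84 and 0.67 in sham CT20 replicates 1, 2 and 3, against 0.21 in the highest ADX library of that time.

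**Figure D1:**
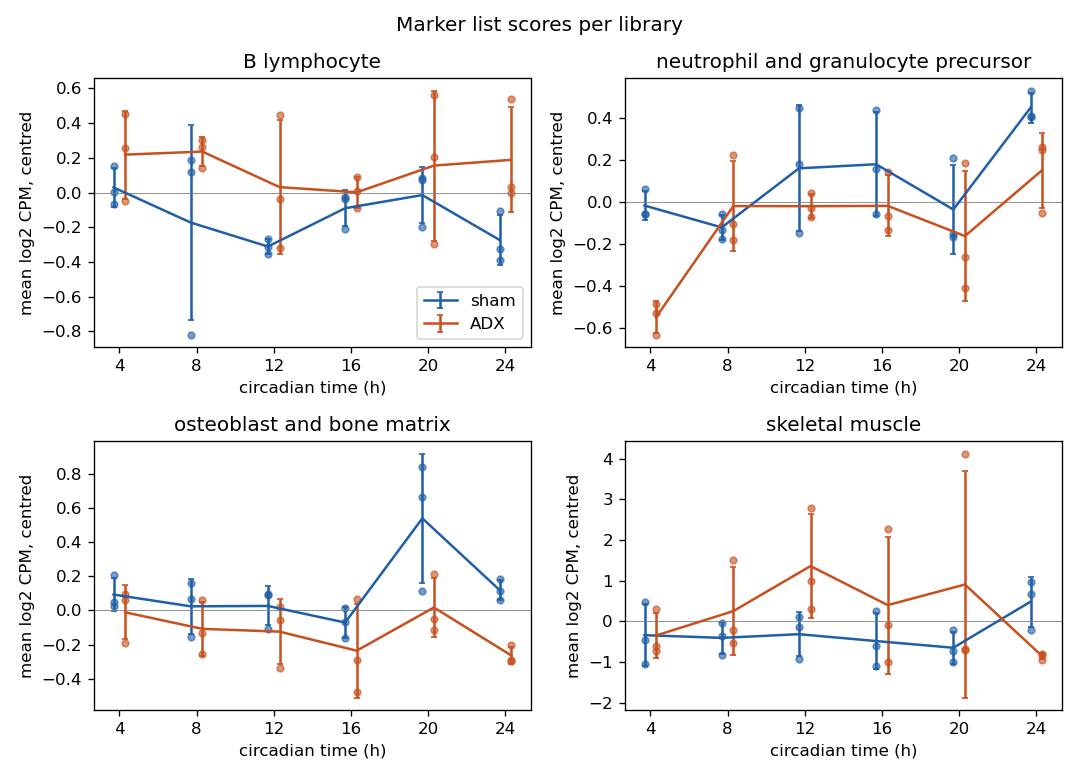
Scores of 4 marker lists (vertical axis, mean centred log2 CPM of the members) against circadian time in hours, with points for libraries and lines with bars for the mean ± SD (n = 3) of sham and ADX. The B lymphocyte score was higher in ADX by 0.28 over the 6 times, and the skeletal muscle score of 1 ADX library at CT20 stood at 4.13.

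The set test camera with a preset correlation of 0.01 called 15 of 31 lists, 4 higher and 11 lower in ADX, and called 0 with an estimated correlation. The rotation test fry, which does not compare a list with other genes, gave adjusted p = 0.0065 for osteoblast, 0.0429 for neutrophil and 0.0434 for B lymphocyte genes. Stria vascularis genes had a median log2 fold change of -0.08 (camera adjusted p = 1.2e-05 with the preset and adjusted p = 0.397 with an estimated correlation), with Esrrb at -0.16 among the members passing adjusted over the list alone. Spiral ganglion neuron genes had a median of 0.09 and 16 of 16 positive values (adjusted p = 1.8e-04 with the preset, adjusted p = 0.504 with an estimated correlation), 0 of which passed in edgeR either over all genes or adjusted over the list alone. Of 19 hair cell genes 8 had a positive value, and the list's camera adjusted p was 0.943 with the preset (lower in direction) and adjusted p = 0.978 with an estimated correlation. Without the 4 libraries of highest Gh, and without the 5 with Gh over 50 CPM, the hair cell list was also lower in direction. Both sets leave 1 library at sham CT08, so their tests rest in part on that library and are not given. Skeletal muscle genes had a median of 1.31 (adjusted p = 0.0020 with the preset, adjusted p = 0.578 with an estimated correlation), which turned negative in direction without the 3 libraries of highest muscle level (adjusted p = 0.853), and whose camera adjusted p was 0.0868 without ADX CT20 replicate 3 alone.

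Transcripts known to be induced by glucocorticoids had small differences over the mean of the day. Of 26 measured members, 3 had a positive log2 fold change, and the median was -0.06. Dusp1, a phosphatase of MAP kinases (ENSMUSG00000024190, chromosome 17, 26505590 to 26562128), fell from 42.2 ± 5.45 to 35.9 ± 5.16 CPM (SD, n = 18 each; log2 fold change -0.23 ± 0.04, edgeR adjusted p = 0.0206). It was the only member to pass over all genes, while Dusp1, Errfi1 and Cebpd passed adjusted over the list alone. The edgeR adjusted p of Dusp1 was 0.0737 without the 4 libraries of highest Gh, 0.198 without the 5 with Gh over 50 CPM, 0.177 without the 4 picked by hand and 0.0507 without ADX CT24 replicate 1. Camera gave the list adjusted p = 4.7e-05 with the preset correlation and adjusted p = 0.384 with an estimated correlation. The glucocorticoid receptor gene Nr3c1 had a log2 fold change of 0.02 ± 0.03 and the mineralocorticoid receptor gene Nr3c2 one of 0.10 ± 0.04, and neither passed.

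At single times the question was at which hour the absence of the adrenals was visible. At CT12 the mean of the co-chaperone gene Fkbp5 was 112 ± 23.1 CPM in sham and 58.2 ± 13.95 CPM in ADX (SD, n = 3), that of Zbtb16 98.1 ± 22.2 and 49.4 ± 15.6 CPM, and that of Tsc22d3, which encodes GILZ, 200 ± 9.74 and 140 ± 26.5 CPM. At CT04, CT16 and CT24 the mean of Fkbp5 was also lower in ADX (38.8 ± 1.53 and 30.4 ± 8.29, 69.2 ± 11.8 and 61.1 ± 6.33, 47.4 ± 3.07 and 46.1 ± 14.5 CPM in sham and ADX; SD, n = 3), and at CT08 and CT20 it was not (39.6 ± 3.58 and 41.4 ± 1.86, 40.1 ± 1.92 and 46.2 ± 17.2 CPM). The log2 fold changes at CT12 were -0.95 ± 0.21 for Fkbp5, -0.99 ± 0.31 for Zbtb16, -0.52 ± 0.12 for Tsc22d3 and -1.33 ± 0.36 for Hif3a, with edgeR adjusted p of 0.516, 0.796, 0.516 and 0.708. The interaction of status and time in the score of the glucocorticoid-induced list, tested after the data were seen, had a permutation adjusted p = 0.603, so a dependence on the hour was not shown. At CT20 Gas2l2 rose from 0.476 ± 0.0927 to 1.96 ± 0.421 CPM (SD, n = 3; log2 fold change 2.03 ± 0.33, edgeR adjusted p = 0.0218), a call that was lost without any 1 of ADX CT20 replicates 2 and 3 and sham CT20 replicates 2 and 3.

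**Figure D2:**
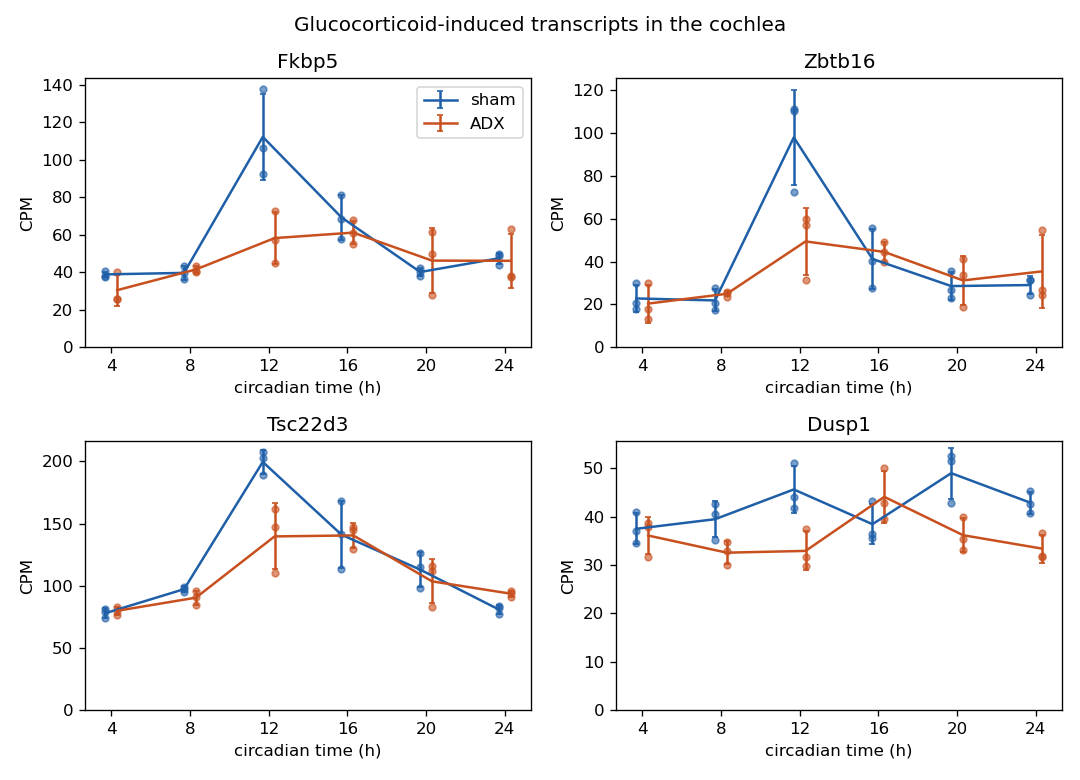
CPM of Fkbp5, Zbtb16, Tsc22d3 and Dusp1 (vertical axes) against circadian time in hours, with points for libraries and lines with bars for the mean ± SD (n = 3) of sham and ADX. At CT12 Fkbp5 averaged 112 CPM in sham and 58.2 CPM in ADX.

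From CT04 to CT24 edgeR called 0, 0, 0, 0, 1 and 0 genes, beside 2097, 966, 1220, 1794, 1690 and 1295 genes at an unadjusted p under 0.05. DESeq2 called 77, 0, 7, 20, 183 and 0 genes at the same times. Leaving out 1 library, the edgeR count at CT20 was 2 without ADX CT04 replicate 1, 73 without ADX CT08 replicate 1, 36 without ADX CT08 replicate 3, 3 without ADX CT20 replicate 1 and 137 without sham CT20 replicate 1, and the highest count at CT04 was 29, without ADX CT20 replicate 3. On simulated counts the CT20 comparison recovered 75 of 100 genes changed by 1 on the log2 scale and 94 of 100 changed by 2. These counts lacked deviations shared by the genes of a library, so recovery in the real data may be lower.

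The next comparison asked which transcripts cycled with a period of 24 h in each status. Core clock genes cycled in both, and 18 of 19 members passed in sham and 18 in ADX, the exception being Rora. Per2 peaked at 13.7 h in sham and 14.4 h in ADX, the repressor gene Nr1d1 at 7.99 and 8.43 h, the output transcription factor gene Dbp at 9.96 and 9.94 h, and Arntl, which encodes BMAL1, at 23.6 and 23.9 h. Per2 (ENSMUSG00000055866) went from 22.4 ± 1.59 CPM at CT24 to 107 ± 6.88 CPM at CT12 in sham, and from 30.7 ± 2.46 to 86.2 ± 15.15 CPM in ADX (SD, n = 3). Outside the clock list, the genes with the smallest p for a shared rhythm were Spon2, Tspan4, Lpl, Por, Usp2, Herpud1, Cyp2a5, Fmo2, Hsp90b1 and Calr. The lipoprotein lipase gene Lpl peaked at 1.42 h in sham and 1.56 h in ADX, and the cytochrome P450 gene Cyp2a5 at 12.4 and 13.4 h with fitted peak-to-trough log2 values of 2.93 ± 0.29 and 2.77 ± 0.29 (SE).

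**Figure D3:**
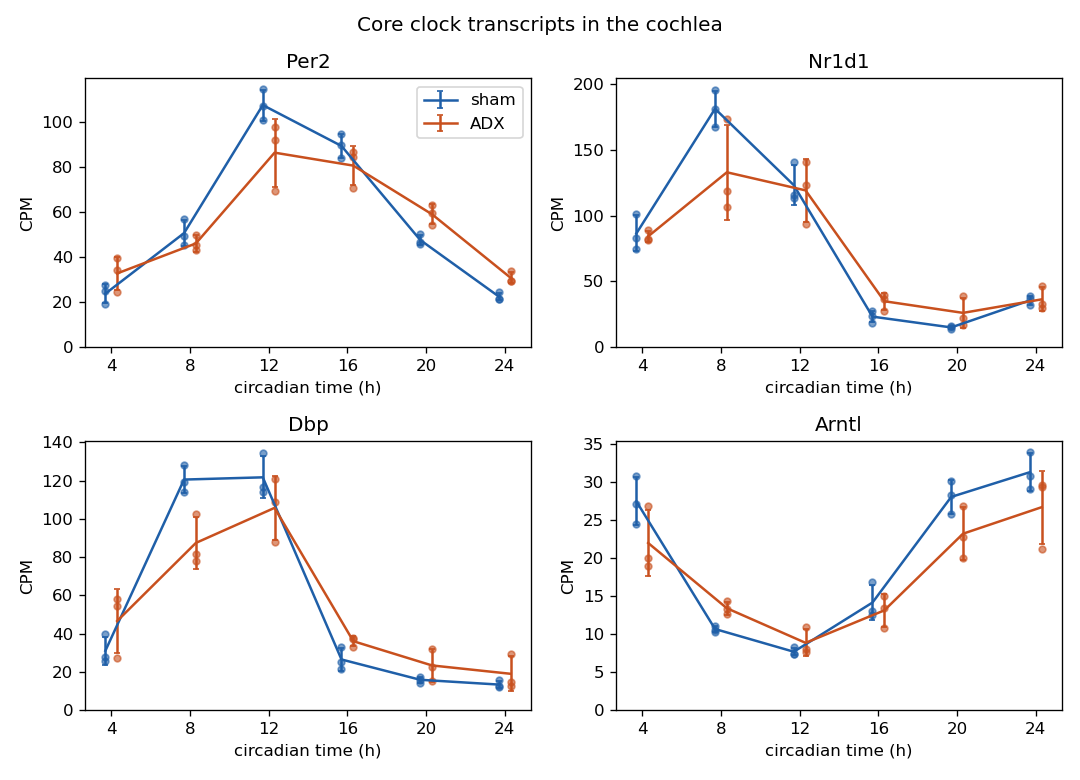
CPM of Per2, Nr1d1, Dbp and Arntl (vertical axes) against circadian time in hours, with points for libraries and lines with bars for the mean ± SD (n = 3) of sham and ADX. Each gene cycled in both statuses, and the peak of Nr1d1 at CT08 averaged 181 CPM in sham and 133 CPM in ADX.

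In edgeR, 3628 of 22556 genes were rhythmic in sham, 2120 in ADX and 1268 in both, where 341 would be shared by independent lists of those sizes. Genes with a fitted peak-to-trough change over 2-fold were more numerous in ADX, with 322 among those rhythmic in sham and 398 among those rhythmic in ADX. The muscle-high libraries were ADX libraries of CT12, CT16 and CT20. Of 15 skeletal muscle genes 5 passed in ADX and 0 in sham, with a median log2 amplitude ratio of 1.80. How much of the larger number in ADX came from muscle carry-over was not tested. The test of a rhythm shared by both statuses called 7331 genes (32.5%). Of the genes rhythmic in sham, 35.1% peaked in the 4 h around CT08 and 26.2% in those around CT20. Depth went with time in part, from 20351081 to 22682581 counts per library at CT12 and from 23972100 to 28661791 at CT24. Since the pools are not given, a technical effect that followed time cannot be told apart from rhythm in these counts. Without ADX CT16 replicate 3 the count in ADX was 1352, and with no filter on low counts it was 1411.

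**Figure D4:**
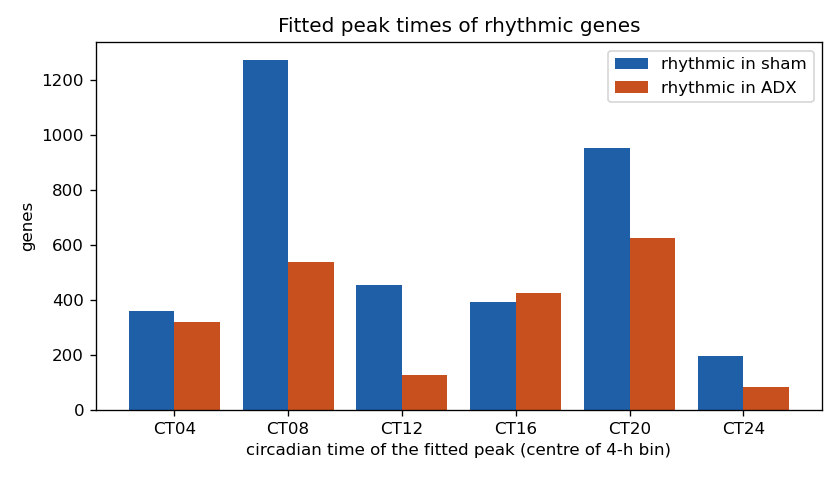
Number of rhythmic genes (vertical axis) by the circadian time of the fitted peak in bins of 4 h (horizontal axis), for genes called in sham and in ADX. The bins around CT08 and CT20 held 1273 and 951 genes in sham, and 539 and 626 genes in ADX.

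Several fixed groups held more rhythmic members in sham than other tested genes did. All 13 heat shock genes passed in sham and 11 in ADX, among them Hspb1, with a peak-to-trough log2 value of 1.67 ± 0.17 (SE) and a peak at 18.3 h in sham. Of 26 glucocorticoid-induced genes 21 passed in sham and 10 in ADX. Tsc22d3 peaked at 13.9 h in sham and 14.97 h in ADX, with peak-to-trough values of 1.27 ± 0.13 and 0.83 ± 0.13. In the T and NK lymphocyte list 8 of 13 genes passed in sham, including Cd8a and Gzma with peaks at 19.4 and 18.7 h. In the extracellular matrix list 9 of 16 passed, including Fbn1 with a peak at 1.17 h. In the Schwann cell and myelin list 7 of 13 passed. They included Mobp and Mog, genes of the central myelin made by oligodendrocytes, with peaks at 14.4 and 13.96 h, and the Schwann cell gene Prx, with a peak at 7.06 h. Under the 5-df test 4 members of that list passed (Fisher's exact test, adjusted p = 0.235). Of 19 hair cell genes, 0 passed in edgeR in sham under the cosine model and 0 under the 5-df test. Fisher's exact test against all other tested genes gave adjusted p = 2.5e-12 for the core clock, 4.9e-10 for heat shock, 9.2e-12 for glucocorticoid-induced, 0.0017 for T and NK lymphocyte, 0.0017 for extracellular matrix and 0.0085 for the Schwann cell and myelin list. The last 3 calls were lost with 1 library left out, the T and NK lymphocyte list without sham CT08 replicate 1 (0.402), sham CT08 replicate 3 (0.238), sham CT12 replicate 1 (0.0726) or sham CT12 replicate 3 (0.0782), the extracellular matrix list without sham CT20 replicate 2 (0.189) or 3 (0.0556), and the Schwann cell and myelin list without sham CT08 replicate 1 (0.0647). Genes of a list are not independent, so these p-values describe this set of libraries.

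Which rhythms depended on glucocorticoids, the purpose stated for the study, was asked with the test of the difference in rhythm itself. Of the 19 core clock genes, each had a smaller fitted amplitude in ADX. The peak-to-trough log2 value was 2.42 ± 0.12 in sham and 1.62 ± 0.11 in ADX for Per2, 3.61 ± 0.22 and 2.58 ± 0.21 for Nr1d1, 3.59 ± 0.24 and 2.54 ± 0.24 for Dbp, and 2.13 ± 0.15 and 1.55 ± 0.14 for Arntl (SE). The difference passed for 11 of the 19 adjusted over the list alone, and for none over all genes, where the adjusted p of Per2 in edgeR was 0.496. The fitted amplitude was also smaller in ADX for 22 of 26 glucocorticoid-induced genes, with a median log2 ratio of -0.53 beside -0.54 for the core clock list. Smaller amplitudes in ADX were not particular to these lists. Of the 7331 genes with a shared rhythm, 62.4% had the larger amplitude in sham. In the cell cycle list 17 of 18 were smaller in ADX (median log2 ratio -0.80), while in the B lymphocyte list 4 of 15 were (0.57). In both of these lists 0 genes were rhythmic in sham and 0 in ADX. Their fitted amplitudes were thus not told apart from noise, and their ratios show neither lost nor gained rhythm. Among the glucocorticoid-induced genes 1 differed adjusted over the list alone, Angptl4, which peaked at 0.297 h in sham and 5.78 h in ADX. The genes with the smallest p also included Arhgdig, Cd300ld, Fosl2, Cd109, and the pituitary hormone genes Gh, Prl and Pomc, whose highest values lay in sham CT16 replicate 3 or sham CT08 replicate 3.

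Over all genes, edgeR called 0 differences in rhythm, with 805 genes at an unadjusted p under 0.05. A 5-df test of status by time called 0, with 1089 unadjusted, and DESeq2 called 1, which was Per2 (adjusted p = 0.0168). Thus 2360 genes passed in sham but not in ADX and 852 in ADX but not in sham, and for none of them was a difference called. On simulated counts the test recovered 43.3% of genes whose peak-to-trough log2 value of 0.6 was lost in ADX and 71.6% of those with a value of 1, while the median value of the genes rhythmic in sham was 0.33. Recovery in the real data may be lower, since deviations shared by the genes of a library were not simulated. Over the 7331 genes with a shared rhythm, the median amplitude in ADX was 0.869 times that in sham (log2 -0.20, jackknife SE 0.22 over libraries), which lies within its error of no change. Of these genes, 96.7% had peaks in sham and ADX within 4 h of each other. The test of a shared rhythm averages both statuses and so favours genes with similar peaks. This share therefore does not show that peaks were kept.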

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

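The times of the column names, the removal of sets of libraries (3 muscle-high, 4 of highest Gh, 5 with Gh over 50 CPM, 4 picked by hand for pituitary transcripts) and the list tests leaving out libraries were chosen after seeing the data; the other settings were planned. Where a value moved, the cause was not tested unless stated. ADX versus sham, mean of 6 circadian times, called 162 genes, against 187 with DESeq2's scaling (77 higher, 110 lower), 133 without a filter, 126 in an additive model, 119 without muscle-high libraries and 165 without the 4 of highest Gh, while it was 645 in DESeq2, 682 with makeup covariates, 9 without the 5 with Gh over 50 CPM and 5 without the 4 picked by hand, which leaves fewer samples. The highest-Gh set leaves 1 library at sham CT08, the hand-picked set 1 at ADX CT24 and the set of 5 leaves 1 at both, and the lone sample is assumed to vary like the other groups. The lone sham CT08 library, replicate 1, had the lowest B lymphocyte score of the 36 libraries, at -0.82. Without the 4 of highest Gh the log2 fold change of Ighm went from 0.33 to 0.45. The results of that set therefore do not show the effect of pituitary carry-over alone. Leaving out 1 library gave 15 to 299.

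ADX versus sham at CT04 called 1 gene without a filter, 77 in DESeq2, 9 without muscle-high libraries, 5 without the 4 of highest Gh, 2 without the 5 with Gh over 50 CPM, 2 without the 4 picked by hand, 25 in its 6 samples alone, and 0 to 29 leaving out 1 library (1 without ADX CT04 replicate 2, 4 without ADX CT04 replicate 3 or ADX CT20 replicate 2, 29 without ADX CT20 replicate 3, 2 without ADX CT24 replicate 1, sham CT12 replicate 1 or sham CT16 replicate 3, 3 without ADX CT24 replicate 2 or sham CT20 replicate 2). ADX versus sham at CT12 called 7 in DESeq2, 1 with makeup covariates, 2 without muscle-high libraries and 0 to 2 leaving out 1 library (2 without ADX CT12 replicate 1). ADX versus sham at CT16 called 2 without a filter, 20 in DESeq2 and 0 to 5 leaving out 1 library (5 without sham CT16 replicate 1, 2 without replicate 2). ADX versus sham at CT20 called 6 without a filter, 183 in DESeq2, 0 with makeup covariates, 0 without muscle-high or hand-picked libraries, 0 in its 6 samples alone (1690 unadjusted in the planned fit), and 0 to 137 leaving out 1 library. ADX versus sham at CT24 called 16 in its 6 samples alone and 0 to 1 leaving out 1 library (1 without ADX CT24 replicate 3). ADX versus sham at CT08 called 1 without the 5 with Gh over 50 CPM and 0 in edgeR and DESeq2 under each other setting (966 unadjusted).

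Rhythm in sham ranged over 2748 to 4185 leaving out 1 library, and rhythm shared by both statuses over 6642 to 7650. Rhythm in ADX was 1411 without a filter and 1352 (without ADX CT16 replicate 3) to 2431 leaving out 1 library. The difference in rhythm between ADX and sham was 1 in DESeq2 and 0 to 1 leaving out 1 library (1 without sham CT16 replicate 3). The median amplitude ratio ADX over sham (log2) was -0.30 to -0.10 leaving out 1 library and -0.07 without muscle-high libraries. Fixed gene lists, ADX versus sham, gave 0 calls with an estimated correlation and 11 to 18 leaving out 1 library; fixed gene lists, rhythm in sham, gave 11 with the 5-df test, 6 to 9 leaving out 1 library and 5 without the 2 sham CT20 libraries of highest osteoclast score. The list skeletal muscle, ADX versus sham, turned lower without muscle-high libraries (adjusted p = 0.853). Of the values of named genes in fits leaving out 1 library, 4394 kept their side of the threshold, 284 lost it, 2 gained it and 0 reversed; 31 sign changes of genes called in neither fit, over all settings, were not counted as reversals.

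The replicate block gave 152 genes for the mean and 1 at CT04. Same-numbered libraries did not detectably deviate together: 1 of 18 pairs had a correlation above 0.1 (from -0.10 to 0.11), and own numbers correlated best in 3 of 18. No pairing by number was thus detected, but the labels do not say what the numbers mark. On simulated counts a log2 change of 0.3 was recovered in 58.2% of genes.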

Other observations

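The tests of tissue carry-over, of single libraries and sets of libraries, of the amount of marrow tissue and of adrenalectomy as the source of Gh, the splits of the mean comparison, the test of the clock amplitude by exchange of status, the random halvings, the tests of list rhythm with libraries left out and the choice of the osteoclast genes were made after the results were seen. Of 9 measured genes of osteoclasts, the cells that break down bone, 6 were rhythmic in sham and 0 in ADX by edgeR's test. Fisher's exact test of the sham count against other genes gave adjusted p = 0.0048, and the call was lost without sham CT08 replicate 1 (0.0647), sham CT12 replicate 1 (0.0726), sham CT20 replicate 2 (0.0630), sham CT20 replicate 3 (0.0816) or sham CT24 replicate 2 (0.0815). Acp5, the tartrate-resistant acid phosphatase gene, had a peak-to-trough log2 value of 0.95 ± 0.17 in sham and 0.08 ± 0.18 in ADX (SE), and the cathepsin K gene Ctsk 1.15 ± 0.23 and 0.13 ± 0.23, with sham peaks at 21.8 and 20.9 h. At CT20 Acp5 averaged 159 ± 35.4 CPM in sham and 106 ± 22.6 CPM in ADX (SD, n = 3). The difference in rhythm passed for 4 of the 9 adjusted over the list alone (Acp5, Mmp9, Ctsk and Atp6v0d2) and for none over all genes. It passed for 0 without ADX CT08 replicate 3, ADX CT12 replicate 3, sham CT20 replicate 3 or sham CT24 replicate 2, and for 1 without sham CT24 replicate 1.

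Of 12 osteoblast and bone matrix genes 3 were rhythmic in sham and 0 in ADX by edgeR's test, and the difference in rhythm passed for 0 adjusted over the list alone. The count in sham was 1 without sham CT12 replicate 3, sham CT20 replicate 2 or sham CT20 replicate 3, the count in ADX was 0 to 2 leaving out 1 library (2 without ADX CT24 replicate 1), and 7 of the 12 passed in sham under the 5-df test (Fisher's exact test, adjusted p = 0.0056, against 0.571 under the cosine model). The collagen gene Col1a1 had a peak-to-trough log2 value of 0.95 ± 0.24 in sham, with a peak at 21.99 h, and 0.16 ± 0.24 in ADX. The median log2 ratio of amplitudes in ADX over sham was -1.62 for the osteoblast and -1.33 for the osteoclast list, and the osteoblast value was -1.05 without ADX CT20 replicate 2. In the osteoblast score sham CT20 replicates 2 and 3 stood above all other libraries, at 0.84 and 0.67, with 0.21 as the next highest. Their osteoclast scores were 0.55 and 0.73, beside 0.58 and 0.79 in sham CT24 replicates 1 and 2. Without the 2 sham CT20 libraries, where the lone sample left at that time is assumed to vary like the other groups, 4 osteoclast genes were rhythmic in sham (Fisher's exact test, adjusted p = 0.160), the difference in rhythm passed for 1 adjusted over the list alone, 1 osteoblast gene was rhythmic in sham and 1 in ADX, the osteoblast and osteoclast ratios were -1.11 and -1.21, and the peak-to-trough value in sham was 0.80 for Acp5 and 0.53 for Col1a1. The cold-inducible RNA-binding gene Cirbp cycled in both, with peaks at 6.80 and 6.57 h and peak-to-trough values of 1.25 ± 0.14 and 1.17 ± 0.14.

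For the 162 genes called between ADX and sham, 1 of 100 splits of status within time, the real one, gave as many genes. The highest other gave 112. A count of 162 was thus rare among the splits, but 100 splits made after the result was seen do not exclude chance. Without the 3 muscle-high libraries the log2 fold changes of the called genes were a median 1.03 times as large. Without ADX CT24 replicate 1 they were 0.970 times as large with all 162 signs kept, while 15 genes passed. The genes were chosen with these libraries included, and each library is a small part of the ADX mean. The ratios could therefore hardly have fallen far, and they do not exclude either as a source. Less marrow tissue would move its cell types alike, but the B lymphocyte minus granulocyte score was higher in ADX by 0.48, above the sham median in 15 of 18 libraries (permutation p = 2.1e-04, 100000 resamples, two-sided), which argues against it as the whole cause. The granulocyte and erythroid scores differed by -0.21 and -0.17 (permutation p = 0.0051 and 0.0469) and did not differ detectably from each other (permutation p = 0.651), so for these genes less marrow tissue cannot be told apart from fewer or less active cells of these kinds. A change in the makeup of blood-forming tissue after adrenalectomy may lie behind part of the list, but makeup and expression per cell were not separated.

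The clock amplitude was weighed next. With fits on log2 CPM, the median amplitude of 19 clock genes in ADX was 0.692 times that in sham (log2 -0.53, jackknife SE 0.17), with permutation p = 1e-05, the smallest that 100000 exchanges of status can give (highest other 0.53). Without ADX CT24 replicate 1, whose clock genes read 3.7 h ahead of its label, the value was -0.47, and without the muscle-high libraries -0.54. Leaving out any 1 library gave -0.57 to -0.45. These values argue against either as the whole source, while a part due to ADX CT24 replicate 1 is not excluded. With each library placed at the time read from the other part of the clock genes, the median log2 ratio was -0.25 (jackknife SE 0.12). This met the bound of -0.27 set for an explanation by a spread of phase between animals, by less than its error. Of 100 random halvings, which gave -0.39 to -0.23, 23 met the bound. A spread of phase may thus account for part of the loss and cannot be told apart from lower amplitude in each animal. The spread of these times within groups was 1.28 h in ADX and 0.621 h in sham (SD; permutation p = 0.469).

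Pituitary hormone transcripts stood in a few libraries, with Gh over 50 CPM in 5 libraries, 3 of them sham and 2 ADX. Over the 36 libraries, 11 further pituitary markers not looked at before had a median Spearman rho with Gh of 0.43 across libraries, which is consistent with carry-over of pituitary tissue at dissection. Gh did not differ detectably by status (permutation p = 0.608), and the library of highest Gh was sham, which argues against adrenalectomy as the source. Between ADX and sham 165 genes passed without the 4 libraries of highest Gh, 9 without the 5 over 50 CPM and 5 without 4 picked by hand, with fold changes of the 162 genes a median 1.002, 0.969 and 0.961 times as large and standard errors 1.13, 1.19 and 1.14 times as large; both sets of low count leave out ADX CT24 replicate 1, without which alone 15 passed.

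Other counts were set against splits in the same way. Rhythm in sham (3628) was reached by 1 of 100 exchanges of time, the real one (highest other 613), and rhythm in ADX (2120) by 1 (highest other 21). The shared rhythm (7331) was reached by 1 (highest other 123) and the 7 lists rhythmic in sham by 1 (highest other 2). Chance is thus an unlikely source of the counts of rhythmic genes. Most exchanges held so few rhythmic genes that Fisher's exact test of the lists had almost nothing to find. They therefore do not test the 7 lists. A technical effect that followed time would also be broken up by the exchanges, so they do not bear on it. For the 15 lists called between ADX and sham chance remains open, since 8 of 100 splits gave as many (highest other 18). It also remains open for the amplitude ratio over all genes (18 of 100, highest other 0.34 on the log2 scale). For the difference in rhythm all 100 splits gave at least the real 0 (805 unadjusted in edgeR, 1 in DESeq2), as any split must, so these splits decide nothing; 2 of the 99 others gave more than 2 genes (26 and 159, the highest). At single times 10 splits of 6 samples are too few for a share under 0.05. As many genes were given by 10 of 10 splits at CT04, CT08, CT12, CT16 and CT24 (real 0 in edgeR, highest others 0, 0, 0, 5 and 1) and by 3 of 10 at CT20 (real 1, highest other 50).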
